A study of Mus musculus with 4 samples.

How the data were processed

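Polyadenylated RNA of 4T07 mouse mammary carcinoma cells was measured by RNA-seq in 2 samples labelled control and 2 labelled as overexpressing Six2, grouped by their titles. Six2 itself had 0 reads in both control libraries, 3 in Six2 replicate 1 and 0 in Six2 replicate 2, so the values do not show the overexpression that the labels name. Per the labels' protocols, RNA was taken 48 hours after plating and libraries were made with a TruSeq stranded mRNA kit. The submitters' processing notes name bcl2fastq 1.8.4, FastQC 0.11.5, TopHat2 2.1.1, Bowtie2, SAMtools 1.5, Picard 2.9.4, HTSeq 0.8.0 and the builds GRCm38 and mm10. The gene annotation, the gene lengths, the strand setting of the counting and the treatment of reads shared by genes are not given in the sources used here, so values of overlapping genes, antisense genes and near-identical gene copies are uncertain. The authors deposited RPKM values, reads scaled by gene length and by the library's read total, in a table of 24421 genes, and no scaling between libraries beyond the read total is stated. The fate of reads from an introduced coding sequence is likewise not given.

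The deposited RPKM values of a gene are whole multiples of what 1 read is worth. From these steps the read totals were recovered as 43110985, 41881864, 49910629 and 81524250 for control replicates 1 and 2 and Six2 replicates 1 and 2. All 14459 genes above 0 in 3 or more libraries gave whole reads within 0.001 reads. A factor common to a gene's reads and its length cannot be seen this way, so a read number may be understated. A value of 0 allows up to 3 reads, which on a gene of 1 kb is 0.0696, 0.0716, 0.0601 and 0.0368 RPKM in the same order, and such limits cover counting error only. The 10 most abundant genes held 5.81%, 5.33%, 6.15% and 5.61% of reads. Depth was highest in Six2 replicate 2, whose low values are the more precise. Pearson correlations across genes, which are not independent replicates, lay between 0.96 and 0.985 for the 6 pairs of libraries.

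Before the data were examined, a count test had been chosen. The values turned out to be RPKM, so limma 3.58.1 in R 4.3.3 was used instead. It fitted a linear model of log2(RPKM + 1) on group, with moderated variances following a trend on mean expression. The test took the 10654 genes at 1 RPKM or more in at least 2 libraries and was two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(RPKM + 1) scale, which understates the change of low genes, and ratios are of mean RPKM. Before the data were examined, 33 gene lists were fixed; camera was run on the same log2 values for the 32 with at least 3 tested genes, with a preset correlation of 0.01, beside an estimated correlation and fry. The list of 13 mitochondrially encoded genes had 0 members in the table. Member numbers given for a tested list are of its tested genes, often fewer than the genes listed. Benjamini-Hochberg adjustment was over the 32 lists, and members were also adjusted over the list alone. That adjustment of members does not allow for the number of lists. With an estimated correlation camera works on the residual degrees of freedom, 2 for the group fit. A failure to pass there therefore says little.

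The rule for named genes, also fixed before the data were examined, took Six2, Sox2, Nanog, Pou5f1, Cdh1 and Vim whatever their result. It also took the called genes with the largest fold change, up to 12 in each direction. These had all 4 libraries apart, a mean of at least 10 CPM in the higher group and no clone, model or pseudogene name. Libraries were compared in RPKM, in place of the scaled CPM that the rule names. From each list the rule took up to 3 called members in each direction or, with none called, the 2 of highest mean CPM. Some genes that the rule or a list would name are not reported here. Other names are said to be chosen after their values were seen, and this holds for each member named because it passed adjusted over its list alone. Coordinates and identifiers come from GENCODE annotation of GRCm38, which named 96.6% of the tested genes. The gene lengths recovered from the RPKM steps equalled the exon length in that annotation for 4.27% of genes, so the authors' gene models may differ from it.

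The tests were checked on simulated reads for the 10654 genes of this comparison, with 200 genes changed. The changed genes were drawn only from those with a mean of at least 200 reads, so the rates do not cover genes of fewer reads. Where replicates varied independently, limma-trend recovered 74% of the 1.5-fold, 98% of the 2-fold and 100% of the 4-fold and 8-fold changes, with 21 false calls. Where replicate numbers shifted both groups alike by an SD of 0.317 on the log2 scale, it recovered 0%, 8%, 80% and 100%, with 0 false calls. With the replicate number as a block it recovered 100% at each fold there, with 37 false calls, the shared shift being built in. With independent replicates the block gave 41 false calls. The simulated dispersion of reads was 0.002 with the shared shift and 0.00801 with independent replicates. Each simulation gave every gene the same dispersion, whereas real genes differ in their spread. The rates may therefore overstate how well the test recovers changes in the real libraries. Alternatives tried were relative log expression factors, no filter, a filter of 1 CPM in 2 libraries, a test against a fold of 1.5 and the replicate number as a block. Others were leaving out the 10 most abundant genes, a pseudocount of 0.1 and leaving out each library. Added after the data were seen were voom on the recovered reads, with and without the block, and the removal of each chromosome's median difference. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for the recovery of reads and the plots.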

Results

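RNA from 4T07 cells, a mouse mammary carcinoma line of the Balb/cfC3H strain, was sequenced in 4 libraries. According to the labels, 2 libraries came from control cells and 2 from cells overexpressing Six2, a homeobox transcription factor of the developing kidney, and all cells were harvested 48 hours after plating. The values were RPKM, reads scaled by gene length and by the read total of the library, for 24421 genes. The read totals behind them were 43110985 for control replicate 1, 41881864 for control replicate 2, 49910629 for Six2 replicate 1 and 81524250 for Six2 replicate 2. In these libraries 1 read on a gene of 1 kb was worth 0.0232, 0.0239, 0.02 and 0.0123 RPKM. The labels do not say whether replicates came from separate cultures, so the p-values set the group difference only against the spread between these libraries, which may be technical. That spread was largely shared by replicate number. Across genes, the difference between the control replicates correlated with that between the Six2 replicates at r = 0.818.

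The comparison asked which transcripts differed between control 4T07 cells and cells overexpressing Six2. Six2 itself (ENSMUSG00000024134.11, GRCm38 chromosome 17, 85684277 to 85688274, minus strand, protein coding) was listed at 0 in both control libraries and in Six2 replicate 2, and at 0.0285 RPKM, or 3 reads, in Six2 replicate 1. Over the 2 libraries of a group, 3 reads correspond to 0.0167 RPKM in the control group and 0.0108 RPKM in the group labelled Six2. No fold change is given for Six2, since both groups lay at or under 3 reads. The groups are therefore named here by their labels, and every direction is that of the libraries labelled Six2 against the control libraries.

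In the libraries labelled Six2, Hspb1, which encodes a small heat shock protein, rose from 0.0514 and 0.106 RPKM, which are 2 and 4 reads, to 20.8 and 25.9 RPKM. Krt76, a keratin gene, rose from 1.42 to 10.2 ± 0.976 RPKM (SD, n = 2 per group), and Csn3, which encodes the milk protein kappa-casein, rose from 39.5 ± 5.06 to 171 ± 7.39 RPKM. Perp, which encodes a desmosomal protein, fell from 14.1 ± 1.21 to 0.521 ± 0.217 RPKM, and the simple epithelial keratin gene Krt7 fell from 9.74 ± 1.51 to 0.551 ± 0.118 RPKM. The Notch ligand gene Dll1 fell from 7.10 ± 0.732 to 0.885 ± 0.0375 RPKM. Cdh1, which encodes the adherens junction protein E-cadherin, was at 11.5 ± 4.38 RPKM in control cells and 0.144 ± 0.0589 RPKM in the libraries labelled Six2, a ratio of 79.6. It did not pass the test over all genes (limma-trend adjusted p = 0.0592). The limma-trend adjusted p was 0.0629 with chromosome medians removed and 0.0461 with a filter of 1 CPM in 2 libraries. On the log2(RPKM + 1) scale Cdh1 differed by -3.40 with all 4 libraries. The difference was -3.04 without control replicate 1, -3.77 without control replicate 2, -3.46 without Six2 replicate 1 and -3.35 without Six2 replicate 2.

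Of the 10654 genes tested, 3 were higher and 9 were lower at an adjusted p under 0.05 with limma-trend and Benjamini-Hochberg adjustment. All 12 moved the same way in both replicate numbers, which their selection from these same libraries largely fixed in advance. On the log2(RPKM + 1) scale, which understates the change of low genes, Hspb1 (chromosome 5, 135887919 to 135889563) rose by 4.49 (SE 0.15, adjusted p = 0.0346). The changes of Krt76 and Csn3 were 2.21 (SE 0.121, adjusted p = 0.0397) and 2.09 (SE 0.125, adjusted p = 0.0452). Perp (chromosome 10, 18845020 to 18857073) changed by -3.32 (SE 0.155, adjusted p = 0.0397), Krt7 by -2.79 (SE 0.155, adjusted p = 0.0397) and Dll1 by -2.10 (SE 0.127, adjusted p = 0.0452). Sbsn, which encodes suprabasin of stratified epithelia, fell from 10.3 ± 0.254 to 1.84 ± 0.31 RPKM (adjusted p = 0.0499), and the beta-tubulin gene Tubb2a fell from 11.8 ± 0.297 to 3.07 ± 0.101 RPKM (adjusted p = 0.0453). The other 4 called genes fell outside the naming rule and were chosen after their values were seen. Mcpt8, which encodes a mast cell protease, was at 5.34 and 5.87 RPKM in control cells and had 0 reads in both libraries labelled Six2, at least 206-fold lower when set against 3 reads over the group. Hs3st1, which encodes a heparan sulfate sulfotransferase, fell from 5.20 ± 0.615 to 0.042 RPKM, Gm773 from 8.97 ± 1.01 to 0.585 RPKM, and A630095E13Rik from 4.70 ± 0.446 RPKM to 0 and 4 reads, each with an adjusted p of 0.0397.

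**Figure D1:**
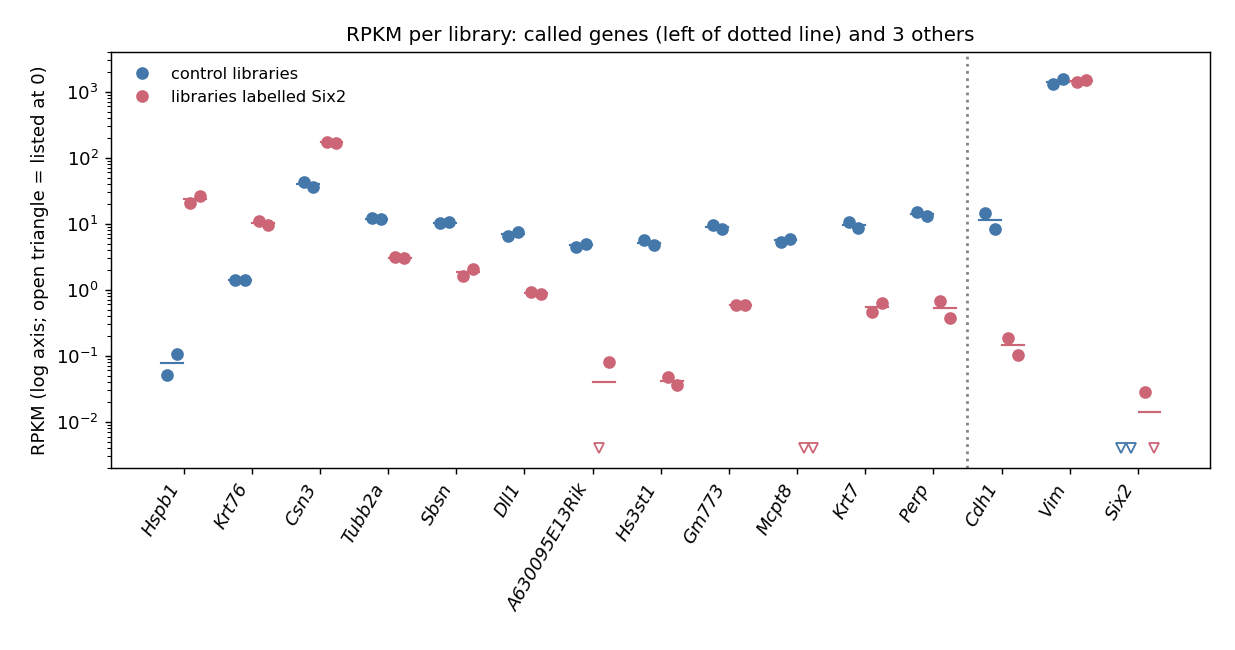
RPKM of each library on a log axis for the 12 called genes and for Cdh1, Vim and Six2; each point is a library, each bar the mean of 2 libraries, and an open triangle marks a value listed at 0. The control and Six2-labelled libraries of each called gene lie apart, and Hspb1 goes from 0.0514 and 0.106 RPKM to 20.8 and 25.9 RPKM.

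At an unadjusted p under 0.05, 784 genes were higher and 1029 lower, where 533 of either direction were expected by chance. All 4 libraries lay apart by group for 47.4% of the genes tested, against 33.3% by chance for 2 libraries against 2. Of those genes 44 were at least 2-fold higher and 200 at least 2-fold lower on the log2(RPKM + 1) scale. Both chance figures assume that the 4 libraries are exchangeable, which a shift shared by replicate number would break. None of the 12 calls held with no filter on low values (smallest adjusted p = 0.0519, 2503 genes at an unadjusted p under 0.05), and 1 higher and 0 lower genes passed a test against a fold of 1.5. The calls were 2 higher and 9 lower without control replicate 1, 6 and 25 without control replicate 2, 4 and 31 without Six2 replicate 1, and 18 and 50 without Six2 replicate 2. Without control replicate 1 the calls of Krt76 and Dll1 (adjusted p = 0.0577 each), A630095E13Rik and Hs3st1 (0.0507 each), Sbsn (0.0928) and Tubb2a (0.115) ended. Without control replicate 2 those of Sbsn (0.0571) and Tubb2a (0.0643) ended. The call of Sbsn also ended with relative log expression factors (adjusted p = 0.0511), a pseudocount of 0.1 (0.0522), voom on recovered reads (0.0536) and chromosome medians removed (0.0521). Tubb2a was lost with voom (0.0585) and with chromosome medians removed (0.0521), A630095E13Rik with a pseudocount of 0.1 (0.0596) and voom (0.0661), and Krt7 with voom (0.0517).

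Of the 6 genes tested of the families of Six2, Eya and Dach, 0 passed over all genes, and adjusted over the list alone 3 were higher and 2 lower. Among the higher members Eya1 rose from 0.155 and 0.33 RPKM to 1.54 and 1.49 RPKM and Six4 from 4.20 ± 0.731 to 7.25 ± 0.647 RPKM, and the cofactor gene Eya2 (10.0 to 4.07 RPKM) and Six5 (5.78 to 3.74 RPKM) fell, these members being named after their values were seen. Eya3 differed by -0.11 (SE 0.216). The family as a whole did not pass (camera adjusted p = 0.393). Six4 lies on chromosome 12 and Eya1 on chromosome 1, chromosomes whose tested genes had median differences of 0.25 and 0.32. With chromosome medians removed, Six4 differed by 0.42 and Eya1 by 0.70.

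The pluripotency factors Sox2, Nanog and Pou5f1 were near or at 0. Sox2 was listed at 0 in all 4 libraries. Nanog had 1, 0, 1 and 1 reads and Pou5f1 had 2, 0, 0 and 0 reads in control replicates 1 and 2 and Six2 replicates 1 and 2. Of the 4 pluripotency genes tested, Klf4 was lower adjusted over the list alone (17.9 ± 3.82 to 9.40 ± 0.708 RPKM), and Myc differed by 0.18 (SE 0.243); the list had a camera adjusted p of 0.47. Of 12 mammary and cancer stem cell markers, 3 were lower adjusted over the list alone, with a camera adjusted p of 0.19 for the list. They were Cd24a (161 to 66.4 RPKM), Procr (68.7 to 30.2 RPKM) and the efflux pump gene Abcg2 (1.41 to 0.382 RPKM). Itgb1 differed by -0.24 and Cd44 by -0.15. Cd24a differed by -1.31 with all 4 libraries and by -1.69 without Six2 replicate 1, the Six2-labelled library nearer the control values. Leaving out Six2 replicate 2 instead (49.15 RPKM, against 83.65 RPKM in Six2 replicate 1) makes the difference smaller.

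The epithelial junction and identity genes were lower as a list (median log2 difference -0.41, camera adjusted p = 0.00598; adjusted p = 0.71 with an estimated correlation). Of 14 members tested, 1 was lower over all genes, Krt7, and adjusted over the list alone 4 were lower and 1 higher. The lower members included Cdh1, Krt7 and the keratin gene Krt19 (6.51 to 0.633 RPKM), and the epithelial transcription factor gene Elf3 rose from 2.19 to 4.20 RPKM. Elf3 lies on chromosome 1, whose median difference was 0.32, and its difference of 0.70 was 0.38 with chromosome medians removed (adjusted p = 0.401 over all genes). Krt19 differed by -2.14 with all 4 libraries and by -2.59 without control replicate 2, the control library nearer the Six2-labelled values. Without control replicate 1 instead (8.76 RPKM, against 4.26 RPKM in control replicate 2) the difference is smaller. The abundant keratin genes Krt8 (901 and 789 RPKM) and Krt18 (637 and 540 RPKM in control and Six2-labelled cells) did not pass. Among 12 mesenchymal genes and inducers of epithelial-mesenchymal transition, 0 were higher and 3 lower adjusted over the list alone, namely Snai1 (46.5 to 29.0 RPKM), Sparc (269 to 151 RPKM) and Col5a1 (12.02 to 7.34 RPKM). Vim, which encodes the intermediate filament vimentin, was at 1426 ± 179 and 1475 ± 68.6 RPKM (log2 difference 0.05, adjusted p = 0.872). Fn1, which encodes fibronectin, was at 537 ± 183 and 247 ± 57.1 RPKM (log2 difference -1.10, adjusted p = 0.204). The mesenchymal list did not pass (median -0.17, camera adjusted p = 0.0997).

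Mammary lineage markers went both ways. Of 24 luminal markers 9 were tested. Csn3 was higher and Krt7 lower over all genes, with Krt19 also lower adjusted over the list alone (camera adjusted p = 0.442). Only 6 of the 22 genes of the basal and myoepithelial list were tested, the others lying below the filter. As tested, that list was lower (median -0.46, camera adjusted p = 0.0206, and 0.71 with an estimated correlation). Its lower members adjusted over the list alone were Dll1 and Procr, both held by other lists too. Few markers of other cell types were tested, 4 of 24 for leukocytes, 4 of 22 for fibroblasts and 3 of 18 for endothelium. Among them, 0 of 4 leukocyte genes passed adjusted over the list alone (median -0.66, camera adjusted p = 0.19). The same count was 2 of 4 for fibroblast genes (median -0.53, camera adjusted p = 0.128) and 0 of 3 for endothelial genes (median 0.10, camera adjusted p = 0.643). The fibroblast members that passed were the actin-severing protein gene Gsn (52.4 to 27.3 RPKM) and the complement gene C3 (9.81 and 9.58 RPKM in control cells, 1.54 and 3.89 RPKM in the libraries labelled Six2), and Pdgfra differed by -0.16. C3 differed by -1.60 with all 4 libraries and by -2.07 without Six2 replicate 2, the Six2-labelled library nearer the control values. Without Six2 replicate 1 instead, the difference of C3 is smaller than with all 4 libraries. Cd14 was at 61.9 ± 32.7 and 32.2 ± 13.9 RPKM and S100a8 at 59.2 ± 25.7 and 27.4 ± 8.98 RPKM, whereas Flt1 differed by 0.37 and Egfl7 by 0.10.

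The Notch pathway list was lower (11 members, median -0.46, camera adjusted p = 0.033; adjusted p = 0.71 with an estimated correlation). Dll1 was lower over all genes, and adjusted over the list alone Dll1, Dtx4 (7.03 to 2.90 RPKM), the glycosyltransferase gene Lfng (3.60 to 1.23 RPKM) and the feedback inhibitor gene Nrarp (2.93 to 0.588 RPKM) fell. Dll1 lies on chromosome 17, whose median difference was -0.21, and differed by -1.89 with an adjusted p of 0.0521 once chromosome medians were removed. TGF-beta pathway genes and targets were lower as a list (24 members, median -0.23, camera adjusted p = 0.00505; adjusted p = 0.71 with an estimated correlation). The receptor gene Tgfbr2 was lower adjusted over the list alone (28.5 to 13.5 RPKM). In that list Thbs1 differed by -1.13 (SE 0.417) and Ltbp3 by -0.14 (SE 0.263). YAP/TAZ targets were lower as a list (20 members, median -0.39, camera adjusted p = 0.00766; adjusted p = 0.71 with an estimated correlation). Adjusted over the list alone, Crim1 (21.7 to 10.5 RPKM) and Nuak2 (2.10 to 0.653 RPKM) fell and Ptpn14 (9.98 to 14.4 RPKM) rose, while Axl differed by -0.05 and Asap1 by -0.46. Ptpn14 lies on chromosome 1 too, and its difference of 0.49 was 0.165 with chromosome medians removed (adjusted p = 0.612 over all genes). Of 16 Wnt pathway genes, Wisp1 (1.83 to 0.376 RPKM) and Wnt10b (26.2 to 7.71 RPKM) were lower adjusted over the list alone. Ccnd1 differed by 0.009 and Notum by -0.09, and the list had a camera adjusted p of 0.19.

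Cholesterol synthesis genes were lower as a list (23 members, median -0.37, camera adjusted p = 0.00205; adjusted p = 0.71 with an estimated correlation). No member passed adjusted over the list alone. Of the 23, 20 lay below 0, among them Sqle, which encodes squalene epoxidase (105 ± 18.2 and 67.0 ± 2.12 RPKM). Glycolysis and hypoxia response genes were higher as a list (32 members, median 0.175, camera adjusted p = 0.0206; adjusted p = 0.71 with an estimated correlation). Of these 23 lay above 0, with Pkm at 2487 ± 9.74 and 3265 ± 525 RPKM and Gapdh at 2669 ± 84.7 and 3000.0 ± 86.2 RPKM. G1/S and DNA replication genes were higher as a list (30 members, median 0.11, camera adjusted p = 0.0356; adjusted p = 0.71 with an estimated correlation). Of these 22 lay above 0, with Pcna differing by 0.09 and Dnmt1 by 0.21. From replicate number 1 to 2, in a fit with group and replicate number, the G1/S list moved more, by a median of 0.199. The 30 G2/M genes did not pass (median 0.12, camera adjusted p = 0.0997), Mki67 differing by 0.18 and Top2a by -0.01. Without control replicate 1 the calls of the cholesterol (adjusted p = 0.0941), glycolysis (adjusted p = 0.0788) and G1/S lists (adjusted p = 0.46) ended. The glycolysis call also ended without Six2 replicate 1 (adjusted p = 0.0891), and the G1/S call without Six2 replicate 2 (adjusted p = 0.418).

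**Figure D2:**
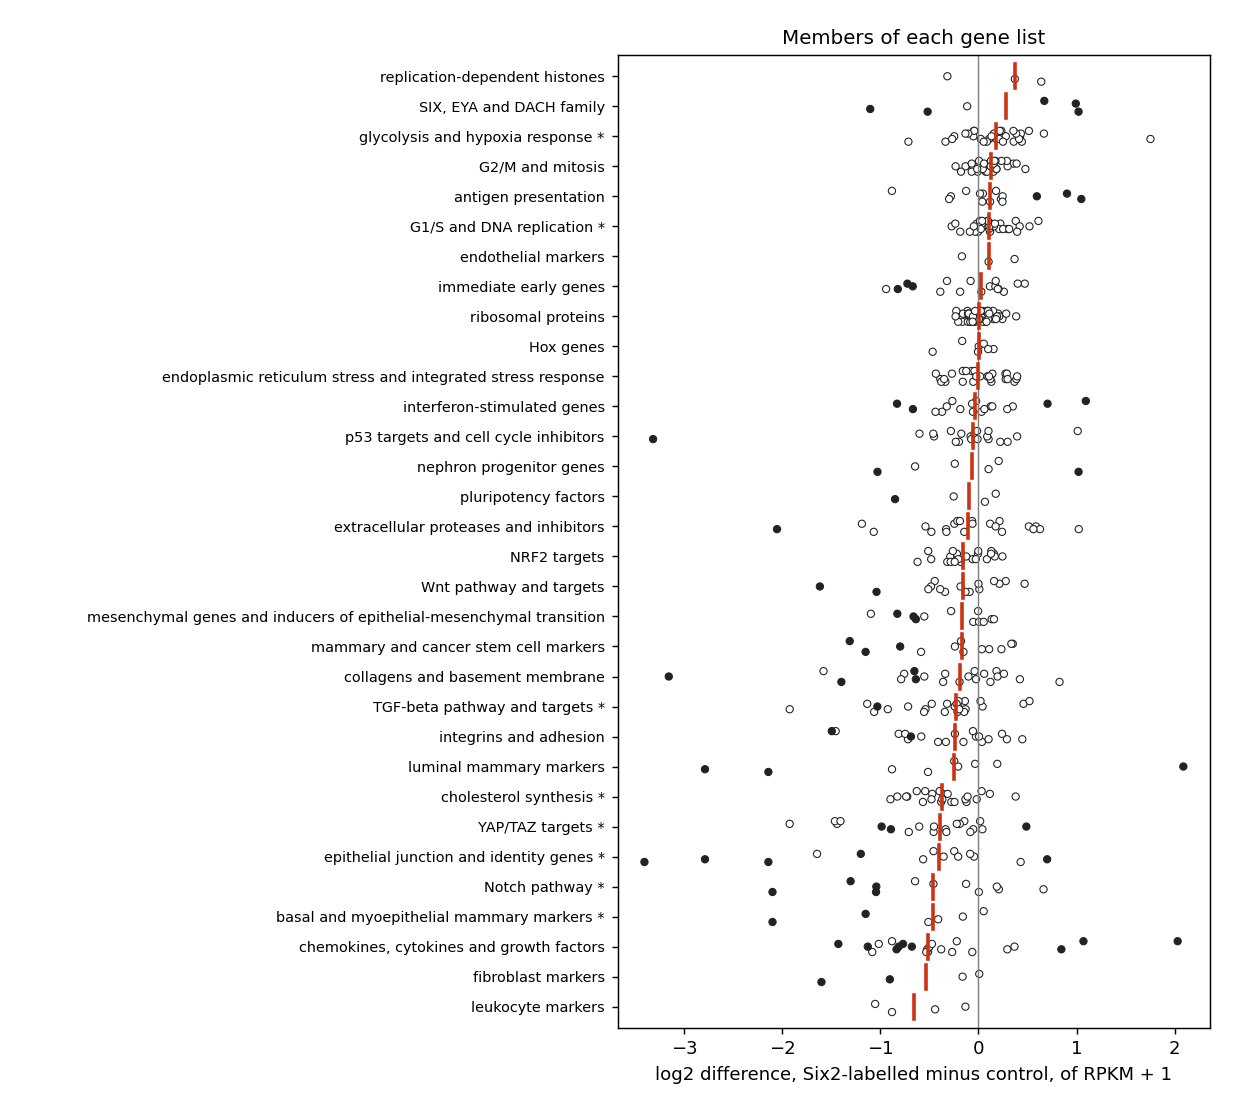
Log2 difference of RPKM + 1, Six2-labelled minus control, for each tested member (circle) of each gene list; filled circles passed adjusted over the list alone, red bars are list medians and a star marks a camera adjusted p under 0.05. The 8 starred lists are 6 with negative and 2 with positive medians, from -0.46 in the basal and myoepithelial list to 0.175 in the glycolysis list.

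In the collagen and basement membrane list 4 of 21 were lower adjusted over the list alone (camera adjusted p = 0.0997). Fbln2, which encodes an extracellular matrix protein of the fibulin family, went from 9.64 ± 3.46 to 0.162 ± 0.0118 RPKM (adjusted p = 0.0592 over all genes). Its log2 difference was -3.16 with all 4 libraries. The difference was -2.82 without control replicate 1, -3.49 without control replicate 2, -3.17 without Six2 replicate 1 and -3.145 without Six2 replicate 2. Col7a1 and Col5a1 differed by -1.40 and -0.64 on the log2 scale, Lama5 by -0.36 and Lamb1 by -0.03. In the integrin and adhesion list Mcam (6.98 to 1.78 RPKM) and Pvrl2 (21.3 to 12.8 RPKM) of 19 were lower adjusted over the list alone, and Itga3 differed by -0.81 (camera adjusted p = 0.0759). In the list of proteases and inhibitors Timp3 of 22 (5.37 and 2.99 RPKM in control cells, 0.398 and 0.055 RPKM in the libraries labelled Six2) was lower adjusted over the list alone, Ctsl differed by 0.22 and Ctsb by 0.12 (camera adjusted p = 0.667). Of 23 chemokine, cytokine and growth factor genes, 6 were lower adjusted over the list alone, namely Pdgfb, Vegfc, Fgf7, Cxcl1, Ccl9 and Pdgfa (camera adjusted p = 0.0759). In that list 3 were higher, namely the alarmin gene Il33 (4.70 ± 1.29 to 22.0 ± 1.32 RPKM), Tgfa (23.9 ± 2.11 to 51.8 ± 12.1 RPKM) and Cx3cl1 (7.67 ± 2.30 to 14.3 ± 0.862 RPKM), and Vegfa differed by -0.27. With all 4 libraries Il33 differed by 2.03 and Tgfa by 1.07. Il33 differed by 2.26 without control replicate 2, by 1.97 without Six2 replicate 1 and by 2.09 without Six2 replicate 2. Leaving out control replicate 1 (3.79 RPKM) keeps the higher control library (5.61 RPKM), which makes the difference smaller than with all 4 libraries. Tgfa differed by 1.31 without Six2 replicate 2, the Six2-labelled library nearer the control values. Without Six2 replicate 1 instead (60.43 RPKM, against 43.26 RPKM in Six2 replicate 2) the difference of Tgfa is smaller than with all 4 libraries.

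In the antigen presentation list 3 of 15 genes were higher adjusted over the list alone (camera adjusted p = 0.0997). They were the immunoproteasome gene Psmb8 (3.75 to 8.86 RPKM) and the peptide transporter genes Tap1 (0.722 to 1.60 RPKM) and Tap2 (2.45 to 5.50 RPKM), all on chromosome 17 between 34187553 and 34216321. That chromosome had a median difference of -0.21, and with chromosome medians removed they differed by 1.26, 0.80 and 1.11. Calr differed by 0.23 and B2m by 0.12. Of 18 interferon-stimulated genes, 2 were higher and 2 lower adjusted over the list alone (camera adjusted p = 0.752). Isg15 (8.94 to 20.4 RPKM) was among the higher, and Irf1 (16.03 to 9.72 RPKM) and Gbp2 (2.56 to 1.01 RPKM) were the lower. Of 17 immediate early genes, Jund, Maff and Klf6 were lower adjusted over the list alone, with Ier3 differing by 0.17 and Fosl1 by 0.26 (camera adjusted p = 0.69). Among 20 p53 targets and cell cycle inhibitors only Perp passed, over all genes and adjusted over the list alone (camera adjusted p = 0.752). Of 6 nephron progenitor genes, Eya1 was higher and Tmem100 (5.67 to 2.25 RPKM) lower adjusted over the list alone, Osr1 differed by 0.21 and Itga8 by 0.10 (camera adjusted p = 0.902). No member passed adjusted over the list alone in 5 further lists. The medians were 0.004 for 51 ribosomal protein genes (camera adjusted p = 0.752), -0.003 for 28 endoplasmic reticulum and integrated stress response genes (0.667) and -0.15 for 22 NRF2 targets (0.335). They were 0.002 for 7 Hox genes (0.99) and 0.37 for 3 replication-dependent histone genes (0.69). Among their most abundant members, Rps2 differed by 0.004, Rplp0 by 0.15, Hspa5 by 0.12, Hsp90b1 by 0.39, Ftl1 by 0.13 and Fth1 by 0.16. Hoxa10 differed by 0.15, Hoxa2 by 0.002, Hist1h2bc by 0.37 and Hist1h1c by 0.64.

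Of the 32 lists tested, 8 passed with the preset correlation and 0 with an estimated correlation, and fry's directional test passed 1, the basal and myoepithelial list (adjusted p = 0.042). The estimated correlation leaves camera 2 residual degrees of freedom, so hardly any list could pass with it. The estimates were 0.766 for cholesterol, 0.445 for epithelial, 0.239 for G1/S, 0.185 for glycolysis and 0.142 for TGF-beta genes. These lie far above the preset 0.01, so the preset p-values of these lists may be too small. For the Notch, YAP/TAZ and basal lists the estimates were -0.1, -0.02 and -0.155. Among the other lists that passed with the preset correlation, fry's directional adjusted p was 0.0531 for Notch and 0.153 for YAP/TAZ. It was 0.304 for epithelial and for TGF-beta, 0.434 for cholesterol, 0.465 for glycolysis and 0.546 for G1/S genes. Fry's test for change in either direction passed 13. The median, mean and test of a list differed in sign for the nephron progenitor genes (median -0.07, mean -0.10, test upward) and the stress response genes (median -0.003, mean 0.003, test upward). They also differed for the Hox genes (median 0.002, mean -0.05, test downward) and the immediate early genes (median 0.03, mean -0.12, test downward). Of the 503 tested genes in at least 1 list, 4 passed over all genes. The passes adjusted over a list alone are weaker, since they do not allow for the number of lists.

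Expression also differed by chromosome, a feature examined after it was seen in the data. The median log2 difference was 0.32 over the 583 tested genes of chromosome 1, 0.25 over 355 genes of chromosome 12 and 0.21 over 491 genes of chromosome 3. It was -0.22 over 317 genes of chromosome 16 and -0.21 over 527 genes of chromosome 17. Between the replicates of a group the chromosome medians had an SD of 0.016, against 0.139 between the groups. With chromosome medians removed, 3 genes were higher and 6 lower, and 15 lists passed camera with the preset correlation. Other genes named above lie on chromosome 1, where with chromosome medians removed Nuak2 differed by -1.22 and Fn1 by -1.42. Crim1 and C3, on chromosome 17, then differed by -0.78 and -1.39, and Gbp2 and S100a8, on chromosome 3, by -1.04 and -1.27. Vegfa, Rps2 and Ier3, on chromosome 17, then differed by -0.06, 0.21 and 0.38, and Lamb1 and Osr1, on chromosome 12, by -0.27 and -0.042. Osr1 thereby changed sign.

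**Figure D3:**
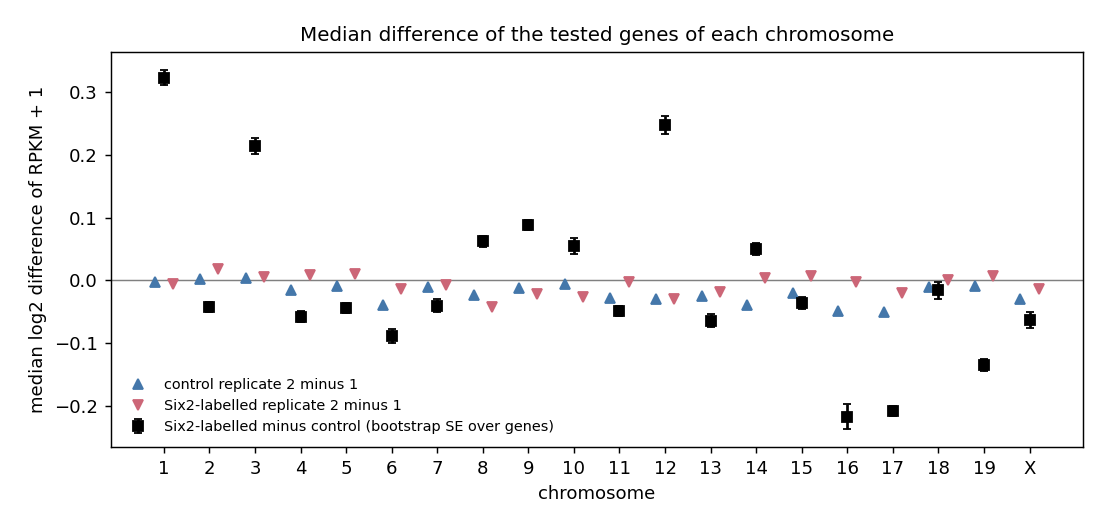
Median log2 difference of RPKM + 1 over the tested genes of each chromosome, for Six2-labelled minus control libraries (squares, with the bootstrap SE over genes) and for replicate 2 minus replicate 1 within each group (triangles). Chromosomes 1, 3 and 12 stand at 0.32, 0.21 and 0.25 and chromosomes 16 and 17 at -0.22 and -0.21, while the triangles lie within 0.051 of 0.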

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

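Voom on recovered reads, with and without the replicate block, the removal of chromosome medians and the replicate block with the estimated correlation were chosen after the data were seen. All 12 called genes had the same direction in every setting run, which adds little, since they were selected from the same libraries. All 12 were called again without the 10 most abundant genes and with a filter of 1 CPM in 2 libraries, 11 with relative log expression factors and 10 with a pseudocount of 0.1. The same count was 9 with chromosome medians removed, 8 with voom, 6 without control replicate 1, 10 without control replicate 2 and 12 without either Six2 replicate. Counts with no filter were 0 higher and 0 lower among 16679 genes tested, where more genes are adjusted for and low genes enter the trend. The test against a fold of 1.5, stricter by its construction, left 1 higher gene, Hspb1, and 0 lower. The other called genes differed by more than that fold, yet had adjusted p from 0.0735 to 0.118 in this limma test. The filter of 1 CPM gave 29 lower genes among 11179, and the cause was not tested. Leaving out a library gave 2 to 18 higher genes, 9 to 50 lower genes and 7 to 13 lists past the threshold. The lowest of these counts of genes came without control replicate 1 and the highest without Six2 replicate 2, and the lone library is then assumed to vary like the other group. Lists past the threshold numbered 0 with the estimated correlation, 1 with fry and 15 with chromosome medians removed. The cause was not tested for the last. Cdh1 had an adjusted p of 0.0461 with the filter of 1 CPM, 0.0629 with chromosome medians removed and at most 0.118 over the settings without a block. Six2, Nanog and Pou5f1 had 3 or fewer reads in all libraries together, and no alternative gives Six2 a fold change. The libraries labelled Six2 were the deepest, at 49910629 and 81524250 reads. Depth would therefore not hide abundant reads on the mouse Six2 gene. Count models and the normalization and filter tied to them were planned but not run, since the values are not counts, and scaling by library size alone is that of the RPKM values themselves.

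The labels do not say that equal replicate numbers share anything. Across genes, the difference between control replicates 1 and 2 correlated with that between Six2 replicates 1 and 2 at r = 0.818, and with 2 pairs this does not settle a pairing. A fit with the replicate block called 2133 higher and 2506 lower genes, and voom with the replicate block 2357 and 2757, both including the 12 genes. Camera with the block passed 11 lists, not including the Notch pathway list (adjusted p = 0.0794), and 0 with the block and the estimated correlation.

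Of 112 genes followed through every setting with a fit, 22 changed sign when a library was left out; none of them was a called gene, and the cause was not tested. The lowest and highest log2 differences were -0.075 and 0.181 for Vim, -0.352 and 0.122 for Eya3, -0.105 and 0.456 for Myc, -0.424 and 0.148 for Ltbp3, -0.088 and 0.106 for Ccnd1, -0.704 and 0.525 for Notum, -0.116 and 0.354 for Ctsb, and -0.114 and 0.063 for Lamb1. They were -0.058 and 0.516 for Calr, -0.018 and 0.199 for Pcna, -0.109 and 0.084 for Top2a, -0.15 and 0.386 for Hspa5, -0.288 and 0.601 for Fth1, -0.277 and 0.483 for Itga8, and -0.241 and 0.245 for Hoxa2. They were -0.547 and 0.222 for Pdgfra, -0.071 and 0.277 for Egfl7, -0.13 and 0.138 for Rps2, -0.023 and 0.765 for Hist1h2bc, -0.209 and 1.489 for Hist1h1c, -0.146 and 0.49 for Ier3, and -0.216 and 0.734 for Fosl1. Top2a was also 0.007 with relative log expression factors and 0.036 with chromosome medians removed, Osr1 was -0.042 with chromosome medians removed, and Hoxa2 was -0.034 with voom on recovered reads.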

Other observations

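The tests of GC content and gene length were set before their results were seen; all other tests of explanations here were chosen after the pattern was seen. Mcpt8 and its neighbour Gzme, both granule protease genes on chromosome 14 (56082166 to 56085273 and 56117626 to 56120625), had 193 and 206 reads and 72 and 73 reads in the control libraries and 0 reads in both libraries labelled Six2. Gzme did not pass over all genes (adjusted p = 0.0655). On either side of the pair, Sdr39u1 and Cenpj, with over 1000 reads in each library, differed by -0.30 and 0.12 on the log2 scale (adjusted p = 0.412 and 0.685).

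Genes also differed between the replicate numbers, and those named here were chosen after their values were seen. In a fit with group and replicate number, 2201 genes were higher and 2570 lower with number 2. The growth factor and cytokine genes Hbegf (11.7 and 7.08 RPKM with number 1, 29.2 and 22.7 RPKM with number 2, control first) and Il11 (22.4 and 15.7, then 58.3 and 42.0 RPKM) were higher. Odc1 of polyamine synthesis and Nop2 and Rrs1 of ribosome assembly were higher too, as was the ribosomal RNA precursor Rn45s (340.2 and 331 RPKM with number 1, 746 and 654 RPKM with number 2, adjusted p = 9.54e-05). Inmt (22.6 and 21.4, then 3.57 and 4.69 RPKM), Txnip, Serpinf1 and Lcn2 were lower. The G2/M list was higher with number 2 (median 0.28, 23 of 30 members past the threshold, camera adjusted p = 2.94e-08) and the cholesterol synthesis list lower (median -0.26, camera adjusted p = 0.0019). Lower with number 2 were also the leukocyte markers (median -0.75, 4 of 4 members lower, camera adjusted p = 0.00424), the epithelial list (median -0.26, 0 members higher and 8 lower, camera adjusted p = 0.0216) and the interferon list (median -0.20, camera adjusted p = 0.0499). Each of these lists had an adjusted p of 0.973 with an estimated correlation, as did every list tested.

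Six2 reads were near absent in the libraries labelled Six2. Loss of reads where genes overlap is argued against by the annotation, in which 0% of the Six2 exon bases are shared with exons of other genes. Labels exchanged between the groups are argued against only as the sole cause, since the control libraries held 0 Six2 reads, which an exchange would also give if the introduced sequence left no reads on the mouse gene. An introduced coding sequence that the mouse reference does not match could leave no reads on the mouse gene, and the 3 Six2 reads found cannot tell this apart from a low level of the introduced transcript. Reads matched to the introduced sequence would be needed, and reads were not analysed here.

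The whole-chromosome shifts between the groups were not a trend of GC content or gene length, since the chromosome 1 median was 0.342 after loess trends on both were removed and 0.323 before. A few clustered genes are argued against as well, because 100% of the 73 blocks of 30 neighbouring genes on chromosomes 1, 3, 12, 16 and 17 lay on their chromosome's side of the median of all genes. In a permutation test with 10000 shuffles of genes over chromosomes, the SD of chromosome medians reached at most 0.025, against 0.139 observed (p = 1e-04, the smallest they can give, over genes and not replicates). Chromosome copy number that differs between the lines may underlie the shifts: all 5 chromosomes kept their sign in both replicate numbers and among both the less and the more expressed genes. This remains a hypothesis found and tested on the same data, an effect of Six2 was not separable from it in this design, and DNA was not analysed here.

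The difference shared by replicate numbers was not one of sequencing depth, since the SD over genes between the control libraries, whose totals are close, was 1.02 times that between the Six2-labelled libraries. Nor was it a trend of GC content or gene length, the correlation of the pairs' differences across genes being 0.817 after loess trends were removed. A candidate explanation is the growth state of the cultures. The G1/S list was higher with number 2 (median 0.199, camera adjusted p = 0.00424), as was the G2/M list. Neither passed with an estimated correlation (adjusted p = 0.973), but every list had that value there, and so few libraries could hardly give a pass. The cell cycle lists do not cover the markers of leukocytes that were lower with number 2, and a difference in cell makeup stays open. Only 4 of 24 leukocyte markers were tested, and Cd14 among them is also a luminal marker, so they are weak evidence of leukocytes in this cell line. The labels give no batch or day, so a difference in handling, or in the carry-over of ribosomal RNA given the Rn45s values, stays open and untested.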
